A study of Danio rerio with 6 samples.

How the data were processed

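RNA was measured in 6 libraries of sorted cells from zebrafish caudal fins at 14 days post amputation, 2 for each of CMP, OMP and osteoblasts, as the sample titles assign them. Per the labels, the sorted cells were lysed directly, RNA was extracted with a column kit for small inputs, and libraries were made with a kit whose name is that of an exome kit. Read alignment with HISAT2 2.2.1 and counting with featureCounts 2.0.3 on build GRCz11 are credited to the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes could not be told apart, and values of near-identical copies such as the hsp70 genes are uncertain.

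The authors deposited 1 table with raw counts per RefSeq transcript, of 75811 rows, 6 of them transgenes. The RPKM values, scaled by transcript length and library size, and the TPM values, which share 1 sum per library, were made by the authors and deposited beside the counts, and were not used for any test here. Transcript lengths in bases were also deposited by the authors and were not used here. In the deposited counts, reads shared by transcripts of a gene appear on each transcript: among 2296 genes with several transcripts and at least 600 reads on the highest, the sum over transcripts was a median of 2.00 times the highest, with a median of 2 transcripts. Therefore the transcript with the highest total over the 6 libraries stood for its gene, for 30837 gene symbols. Of the transgenes, 2 had empty cells in the 3 libraries of replicate 1 and were left out of the tests. Symbols are those of the table; 22227 had a transcript accession in a RefSeq gene table of assembly GRCz12tu, which was used for names only, and no coordinates are given because no annotation of GRCz11 was used here. Of 601 list memberships written beforehand, 591 matched the table.

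Library totals after this choice ran from 3915582 to 5281886 reads (6398411 to 9520310 over all transcripts). The 10 most abundant genes took 22.6% and 17.7% of reads in CMP, 29.3% and 20.2% in OMP and 37.5% and 40.2% in osteoblasts, where col10a1b alone took 9.28% in replicate 2.

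Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr by group, and the quasi-likelihood test on 1 fit of all 6 libraries with group as the only term, which left 3 residual degrees of freedom. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13399 genes tested. The biological coefficient of variation was 0.377. SE of a log2 fold change was the fold change divided by the square root of its F value. CPM values are TMM-scaled and are means ± SD over 2 libraries. Where a group had 1 to 3 reads for a gene, the ratio of depth-scaled reads with its exact 95% counting interval is given, and at 0 reads a bound against 3 reads over the group.

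The design, the alternatives, the gene lists and the rule for named genes were fixed beforehand. The rule takes sp7 and sox9a, the 8 called genes with the largest positive and the 8 with the largest negative fold change among those with a mean log2 CPM of at least 4, non-overlapping groups and a symbol that is not a clone or locus name, up to 4 members of each list by smallest p, members that make up a list count of 5 or fewer, and any member of the osteoblast and cartilage lists. Lists were osteoblast, collagen and fibrous matrix, collagen processing and secretion, cartilage, fin mesenchyme and fibroblast, fin joint, posterior Hox, Wnt, BMP, FGF, Hedgehog, retinoic acid, Notch, cell cycle, early response and heat shock, tendon and ligament, and markers of other cells the gate could hold: epidermis, leukocyte, osteoclast, endothelium, mural cell, pigment cell, nerve and glia, muscle and erythrocyte. Ribosomal protein and nuclear oxidative phosphorylation genes were taken by symbol, which made 27 lists. Mitochondrially encoded genes were measured only as 2 ribosomal RNAs and were not tested as a list. Each was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. No list called with the preset correlation held with the estimated correlation in any of the 3 comparisons. For the osteoblast list the estimate was -0.00595, below the preset 0.01, so its loss did not come from a higher correlation. With an estimated correlation camera refers its statistic to the 3 residual degrees of freedom, which leaves little power. In osteoblasts against CMP that list had camera p = 3.91e-14 with the preset and 0.0035 with the estimated correlation, before adjustment. A call lost with the estimated correlation therefore decides neither for nor against a list. The planned fry test called osteoblast (adjusted p = 7.17e-04 and 4.09e-04) and fin mesenchyme (0.00431 and 0.00211) in osteoblasts against OMP and CMP. In both comparisons it also called collagen processing (adjusted p = 0.01465 and 0.005609), Wnt (0.01396 and 0.01314) and BMP (0.01759 and 0.01314). Further fry calls in both were retinoic acid (0.02354 and 0.01314), mural cell (0.04656 and 0.01314) and pigment cell (0.004833 and 0.01314). It did not call fibrous matrix, Hedgehog, cell cycle or oxidative phosphorylation in these comparisons. With the replicate block fry did call fibrous matrix (adjusted p = 0.009241 and 0.0151) and Hedgehog (0.009241 and 0.01013), among other lists. In OMP against CMP fry called no list (lowest adjusted p = 0.0774).

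Deviations from the group means correlated between libraries of the same replicate number at 0.337 (CMP and OMP), 0.296 (CMP and osteoblasts) and 0.383 (OMP and osteoblasts) over 13399 genes, all above 0.1, so the numbers were taken to pair the samples. The pairing comes from the data, since the labels do not say what a number marks. Within 1 replicate number each group holds 1 library, so no test within a number was possible, and the fit with the replicate number as a block, with 2 residual degrees of freedom, stands in its place.

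The same steps were tested on simulated counts for the 13399 genes. Of genes changed 4-fold, 29.6%, 20.2% and 12.6% were recovered for OMP against CMP, osteoblasts against OMP and osteoblasts against CMP, and of those changed 2-fold 2.94%, 0% and 1.03%, so that many changes of such size could be missed. The share of false calls was 13.5%, 8.70% and 6.67% of 37, 23 and 15 calls. The data gave 261, 1087 and 1424 calls, so the adjusted threshold was stricter in the simulations and recovery in the data may be understated. Each comparison had its own random draw, so differences in recovery between comparisons are not interpreted. A shifted list was called in each comparison, and 0 of 19 unchanged lists. Simulated genes were drawn independently of each other, so this does not test false list calls that come from correlated genes. In the data the correlation was estimated at 0.484 for ribosomal protein, 0.449 for oxidative phosphorylation and 0.566 for early response and heat shock genes.

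Alternatives were other scalings (relative log expression, upper quartile), DESeq2 1.42.0, limma-voom, the legacy dispersion of edgeR, no filter, a stricter filter of CPM of at least 5 in 2 libraries, only the 2 groups compared, the replicate block, a test against a fold of 1.5, and each library left out in turn. The sum over transcripts, DESeq2 with the replicate block, and the counts with the early response and heat shock list left out before filtering and normalization were added after seeing the data. Fits with a library left out held no replicate block, so they ignore the pairing. The overlap of calls against CMP was set beside 20 simulations of unchanged groups. Python 3.11.15 was used for tables and figures.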

Results

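Cells were sorted by fluorescence from adult zebrafish caudal fins that had regrown for 14 days after amputation, and the RNA of 6 libraries was sequenced, 2 from each of 3 groups. The fish carried a tamoxifen-inducible Cre under sox9a control, a reporter that switches from TagBFP to EGFP after recombination, and an mCherry reporter of sp7, the osteoblast transcription factor osterix. The groups are those of the labels, namely chondrogenic mesenchymal progenitors (CMP), osteogenic mesenchymal progenitors (OMP) and osteoblasts. The series text derives the sorted cells from sox9a-expressing somite cells, while the titles give the osteoblasts as EGFP-negative. The stated question was how mesenchymal cells and osteoblasts of the fin are related by lineage. With 1 transcript kept per gene, the libraries held 4234251 and 4868447 reads for CMP, 3922184 and 5281886 for OMP, and 3915582 and 5069304 for osteoblasts (replicates 1 and 2). A set of 8 heat shock genes took 17.03% and 10.8% of these reads in CMP, 19.01% and 7.11% in OMP and 15.4% and 7.08% in osteoblasts. This sign of cell stress thus differed by replicate number more than by group. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers. The labels do not say that the replicates came from separate fish, so p-values measure only the spread between these samples, which may be technical.

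Of the genes behind the sort, sp7 was highest in osteoblasts and sox9a highest in CMP. Endogenous sp7 stood at 2.08 CPM ± 0.132 in CMP, 9.42 ± 1.38 in OMP and 168 ± 9.82 in osteoblasts (SD, n = 2). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment it was higher in osteoblasts than in OMP (log2 fold change 4.16, SE 0.35, adjusted p = 8.71e-05) and than in CMP (6.31, SE 0.41, adjusted p = 1.51e-05). The same test gave a rise of sp7 in OMP against CMP (2.15, SE 0.42, adjusted p = 0.0314, or 0.00775 with the replicate block). That call was lost when any library was left out, with adjusted p from 0.0516 without osteoblast replicate 1 to 0.246 without CMP replicate 2. Sox9a, the transcription factor of cartilage precursors, stood at 46.1 CPM ± 11.3 in CMP, 9.06 ± 2.67 in OMP and 9.95 ± 3.05 in osteoblasts. It was lower in OMP (-2.37, SE 0.43, adjusted p = 0.0231) and in osteoblasts (-2.23, SE 0.44, adjusted p = 0.00855) than in CMP, and was not called between osteoblasts and OMP (0.14, SE 0.46, adjusted p = 0.950). With the replicate block, edgeR gave adjusted p = 9.19e-04 for sox9a in OMP and 4.18e-04 in osteoblasts against CMP. The call in OMP was lost without CMP replicate 1 (adjusted p = 0.178), CMP replicate 2 (0.0973), OMP replicate 1 (0.0655) or OMP replicate 2 (0.166). The call in osteoblasts was lost without CMP replicate 1 (0.0741) or osteoblast replicate 2 (0.0890).

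Reads of the reporters were set beside the sort status in the sample titles, which give CMP as EGFP-positive and sp7-negative, OMP as EGFP-positive and sp7-positive, and osteoblasts as EGFP-negative and sp7-positive. The Cre transgene had 0 reads in all 6 libraries. The mCherry transcript had 3 and 47 reads in CMP, 6 and 62 in OMP and 2455 and 8136 in osteoblasts. It differed by 0.47 (SE 0.88) between OMP and CMP (adjusted p = 0.979, edgeR with Benjamini-Hochberg adjustment) and was higher in osteoblasts than in OMP (7.74, SE 0.93, adjusted p = 6.83e-04). EGFP stood at 836 CPM ± 45.8 in CMP, 999 ± 165 in OMP and 873 ± 108 in osteoblasts, with no call in any comparison. The mCherry reads of the libraries labelled OMP thus went against an sp7-positive sort, and the EGFP reads of those labelled osteoblast against an EGFP-negative sort. The design text of the series describes the mesenchymal cells as sp7-negative. The submitters' short names are Mes-G for CMP, Ob-G for OMP and Ob-GR for osteoblasts, and the names OMP and osteoblast are used here as the labels give them. TagBFP reads stood at 135 CPM ± 101 in CMP, 33.1 ± 25.1 in OMP and 33.0 ± 15.6 in osteoblasts. In edgeR with Benjamini-Hochberg adjustment it was not called against CMP in OMP (-2.0, SE 0.65, adjusted p = 0.208) or osteoblasts (-2.02, SE 0.65, adjusted p = 0.0865). With the replicate block it was lower than CMP in both (-2.01, adjusted p = 8.98e-04, and -1.93, adjusted p = 3.56e-04). Within replicates 1 and 2 the log2 differences were -2.02 and -2.01 in OMP and -1.51 and -2.22 in osteoblasts.

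**Figure D1:**
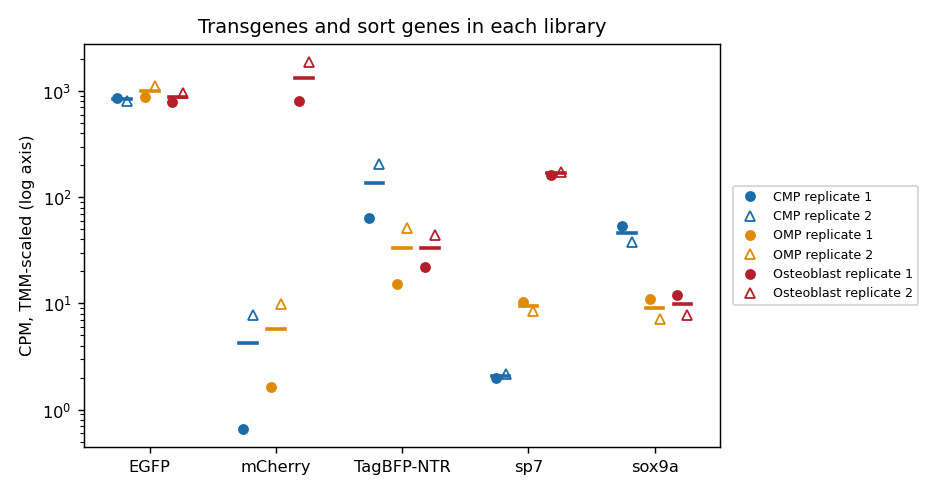
TMM-scaled CPM of the reporter transcripts, sp7 and sox9a in each of the 6 libraries on a log axis, with 1 symbol per library and a bar at each group's mean. In osteoblasts sp7 and mCherry lie above both progenitor groups, and EGFP lies between 796 and 1115 CPM in all 6 libraries.

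Against CMP, the OMP libraries held more RNA of the lysyl oxidase genes loxl3a and loxa, the osteocalcin gene bglap and the type X collagen genes col10a1a and col10a1b. They held less of the homeobox genes msx2b, dlx3b, dlx4b and dlx5a and of the cartilage link protein gene hapln1a. Among called genes with a mean log2 CPM of at least 4 and a symbol that is not a clone or locus name, loxl3a rose most (81.9 CPM ± 22.7 against 3.60 ± 1.78, log2 fold change 4.53, SE 0.46, edgeR adjusted p = 0.00365 with Benjamini-Hochberg adjustment). It was followed by the transcription factor mef2cb (4.32), the FGF-binding protein fgfbp2a (3.8), kank1b (3.62), the heparan sulfate sulfatase sulf1 (3.47), the lubricin gene prg4a (3.44), the calcitonin receptor-like gene calcrlb (3.36) and the aquaporin aqp3b (3.35). With the same limits, the largest falls were those of the alkaline phosphatase alpi.1 (82.1 CPM ± 20.2 against 1296 ± 77.3, -3.98, SE 0.35, edgeR adjusted p = 0.00186 with Benjamini-Hochberg adjustment), ebf1a (-3.97), msx2b (-3.59), ccdc141 (-3.57), cilp (-3.48), cyp1c1 (-3.41), the actinodin gene and2 of fin ray actinotrichia (-3.40) and the natriuretic peptide receptor npr2 (-3.37). Of 13399 genes tested, 132 were higher and 129 lower in OMP, and 202 of these 261 differed at least 4-fold. The fit with the replicate number as a block called 418 and 400, among them all 261. Without CMP replicate 1 or CMP replicate 2, 13 and 12 of the 261 stayed called, without OMP replicate 1 or OMP replicate 2, 96 and 129, and no sign changed.

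The list of osteoblast genes, fixed like all lists before the data were examined, had 6 members higher and 4 lower in OMP among 25 measured, and 15 without a call. Adjusted over the list alone, 12 were higher and 5 lower, and the replicate block called 7 and 5. The 6 were the cadherin gene cdh11 (604 CPM ± 49.97 against 78.6 ± 19.8, log2 fold change 2.94), the osteocalcin gene bglap (2.76), the osteopontin gene spp1 (2.65), the type X collagen genes col10a1b (2.60) and col10a1a (2.41), and sp7. The 4 lower genes were the homeobox genes msx2b, dlx4b (-3.33), dlx3b (-2.51) and dlx5a (-1.77). Values without a call included bglapl at 1.58 (SE 0.50), alpl at 1.18 (SE 0.42), entpd5a at 1.06 (SE 0.31), phex at 0.90 (SE 0.32) and runx2b at 0.74 (SE 0.29). The list's median was 0.74 and camera placed it above other genes (adjusted p = 0.00653), a call that was lost with an estimated correlation (adjusted p = 0.705 with an estimated correlation). Without CMP replicate 1 or CMP replicate 2, 2 of the 10 member calls were left, without OMP replicate 1 or OMP replicate 2, 8, and without either osteoblast library, 9.

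**Figure D2:**
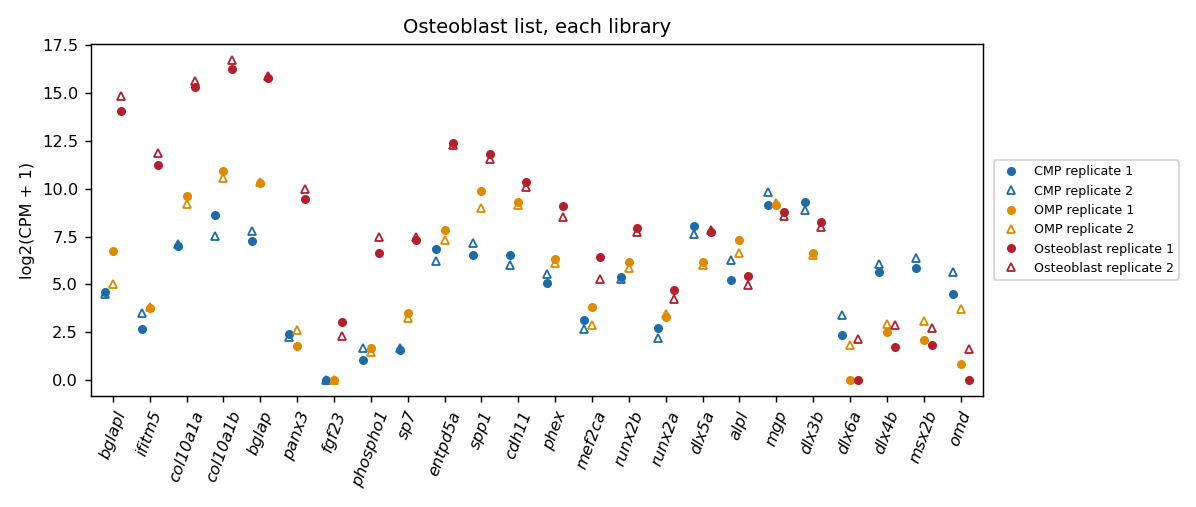
Log2(CPM + 1) of measured members of the osteoblast list, 1 of the 25 not shown, in each of the 6 libraries, with 1 symbol per library. Bglapl, ifitm5, col10a1a, col10a1b and bglap lie highest in osteoblasts, cdh11 and spp1 lie between in OMP, and msx2b and dlx4b lie highest in CMP.

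Cartilage genes did not move together between CMP and OMP. Of 12 measured members, hapln1a, which links aggrecan to hyaluronan (449 CPM ± 75.8 in OMP against 3919 ± 372 in CMP, log2 fold change -3.13, SE 0.28, edgeR adjusted p = 0.00186 with Benjamini-Hochberg adjustment), and sox9a were lower and none was higher. Adjusted over the list alone, 2 were higher and 2 lower, the former being the collagen genes col2a1b (1.28, SE 0.33) and col11a1a (1.14, SE 0.29). Their edgeR p-values with Benjamini-Hochberg adjustment over all genes were 0.0920 and 0.0963, or 0.00408 and 0.00784 with the replicate block. The list's median was 0.28 and its mean -0.15, and camera's direction was down (adjusted p = 0.864). The call of hapln1a held without any library, and that of sox9a was lost without CMP replicate 1 (adjusted p = 0.178), CMP replicate 2 (0.0973), OMP replicate 1 (0.0655) or OMP replicate 2 (0.166).

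**Figure D3:**
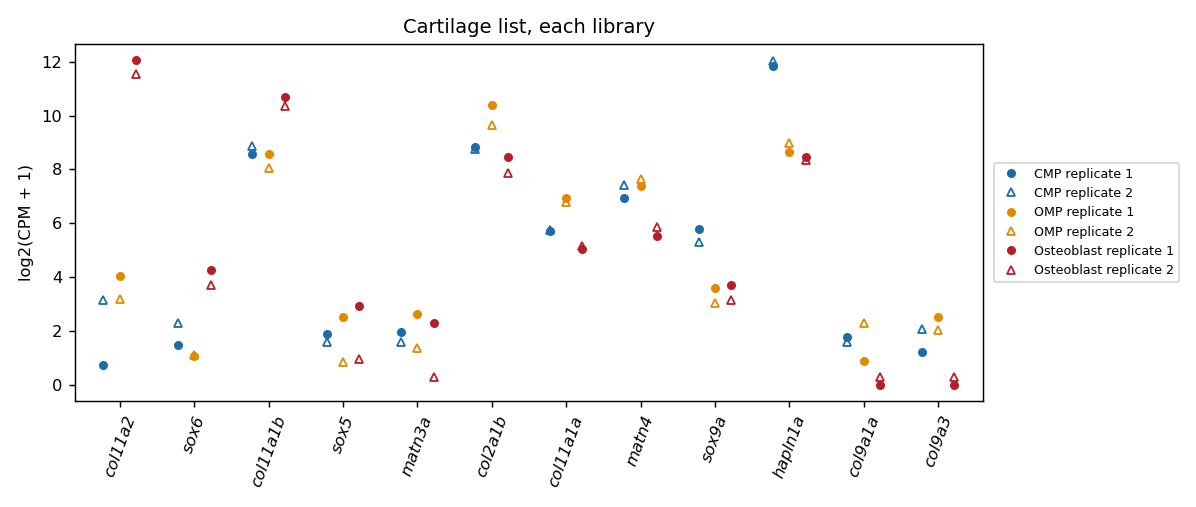
Log2(CPM + 1) of the 12 measured members of the cartilage list in each of the 6 libraries, with 1 symbol per library. Hapln1a and sox9a are highest in CMP, col2a1b and col11a1a in OMP, and col11a2 and col11a1b in osteoblasts.

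Matrix, joint and signalling genes went both ways between CMP and OMP. Of 26 genes of collagens and fibrous matrix, bgna (3.03), the periostin gene postnb (7834 CPM ± 2177 against 1381 ± 14.4, 2.50) and the type I collagen genes col1a1b (1.86) and col1a2 (1.58) rose, and fmodb (-3.21), the versican gene vcanb (-2.29) and the fibronectin gene fn1b (-2.17) fell. Matrix genes adjusted over the list alone gave 9 higher and 5 lower, and the replicate block 10 and 4. Of 29 genes of collagen processing, loxl3a and loxa (1.70) rose and plod2 (-1.80) fell, the same counts adjusted over the list alone, with 4 and 2 under the block. Of 26 genes of fin mesenchyme, pah (1.36) rose and and2, mmp13a (-3.18), dpt (-2.61) and the retinoic acid hydroxylase cyp26b1 (-2.16) fell. Mesenchyme genes adjusted over the list alone gave 3 higher and 9 lower, and the block 3 and 8. Of 9 fin joint genes, prg4a, prg4b (2.90) and evx1 (2.34) rose and hapln1a, gdf6a (-2.52) and the connexin gene cx43 (-2.18) fell, with 4 and 4 adjusted over the list alone. Among 32 Wnt genes the antagonists dkk2 (4.47), wif1 (2.14), sfrp2 (1.39) and notum1b (1.37) rose, while frzb (-3.01), also an antagonist, and rspo1 (-2.91) fell. The Wnt counts were 8 higher and 7 lower adjusted over the list alone and 7 and 6 under the block. Of 27 BMP genes bmp3 (3.13) and the antagonist grem2b (2.56) rose and the antagonist nog1 (-2.91) fell, with 6 and 4 adjusted over the list alone and 5 and 3 under the block. With all 6 libraries camera called none of these 6 lists (lowest adjusted p = 0.103, collagen processing). It called fibrous matrix without CMP replicate 1 (adjusted p = 0.0499) or OMP replicate 2 (0.0316), and collagen processing without OMP replicate 2 (0.0337). Without CMP replicate 1 or CMP replicate 2, 0 of the 4 Wnt genes with the smallest p and 0 of the 3 BMP genes stayed called. The same held for 0 and 1 of the 4 matrix genes with the smallest p, and 2 and 1 of the 4 such fin joint genes. Of the 4 such mesenchyme genes 0 stayed called without CMP replicate 1, CMP replicate 2 or OMP replicate 1. Of the 3 collagen processing genes 1, 0, 1 and 1 stayed called without CMP replicates 1 and 2 and OMP replicates 1 and 2.

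The receptor genes fgfrl1a (-2.47) and fgfr2 (-1.75) fell among 23 FGF genes (1 higher and 3 lower adjusted over the list alone, 3 and 3 under the block). Crabp1b (1.69) rose and cyp26b1 fell among 19 retinoic acid genes (1 and 2 adjusted over the list alone, 1 and 3 under the block). Heyl (3.23) rose among 19 Notch genes, and col14a1a (2.52) and scxb (3.67) rose among 9 tendon genes (3 and 1 adjusted over the list alone, 3 and 2 under the block). Of 18 posterior Hox genes only hoxb13a was called, with 1 read in OMP against 191 in CMP, a ratio of 180.5 with a counting interval of 32.0 to 7167. That list was placed below other genes by camera (median -0.49, adjusted p = 0.0364), but not with the replicate block (adjusted p = 0.0985) nor with an estimated correlation (adjusted p = 0.705 with an estimated correlation). Its call was also lost without CMP replicate 1 (adjusted p = 0.0780), CMP replicate 2 (0.0910) or OMP replicate 1 (0.286). Ribosomal protein genes had no member called among 81 and a median of -0.20 (camera adjusted p = 1.69e-04, adjusted p = 0.947 with an estimated correlation). The ribosomal list had no call without CMP replicate 2 (adjusted p = 0.0858) or OMP replicate 1 (0.286). No member of the Hedgehog (14), cell cycle (28), early response and heat shock (32) or nuclear oxidative phosphorylation (94) lists was called, and none was adjusted over the list alone. Without CMP replicate 1 or CMP replicate 2, 0 of the 2 FGF, 0 of the 2 retinoic acid, 0 of the 1 Notch and 0 of the 2 tendon calls were left. Scxb lost its call when any library was left out (adjusted p 0.0689 to 0.385). Hoxb13a lost its call without CMP replicate 1 (adjusted p = 0.101) or OMP replicate 2 (0.0963).

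Of the markers of other cell types, acta2 and mmp9 were called between CMP and OMP. The smooth muscle actin gene acta2 (-2.79) fell among 12 mural cell genes (3 lower adjusted over the list alone and under the block). The mural list had a median of -0.87, and camera placed it below other genes (adjusted p = 0.0149, and adjusted p = 0.808 with an estimated correlation). The call of the mural list was lost without CMP replicate 2 (adjusted p = 0.188), and that of acta2 without any of the CMP and OMP libraries (0.0547 to 0.169). The matrix metalloproteinase gene mmp9 (2.10) rose among 8 leukocyte genes (1 higher and 1 lower adjusted over the list alone). That call was lost without CMP replicate 1 (adjusted p = 0.101), CMP replicate 2 (0.209) or OMP replicate 1 (0.0915). No member was called of 20 epidermal, 5 osteoclast, 3 endothelial, 3 pigment cell, 6 nerve and glia, 3 muscle and 6 erythrocyte genes. With adjustment over the list alone 1 pigment cell gene was higher, 2 nerve genes were higher and 2 lower, and 1 muscle gene was lower. Under the block ppl was higher and krt4 and krt15 lower among epidermal genes, 1 pigment cell gene was higher, and 1 nerve gene was higher and 2 lower. With all 6 libraries camera called none of these 8 lists, and it placed pigment cell above other genes without OMP replicate 2 (adjusted p = 0.0337) or osteoblast replicate 1 (0.0477).

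Between osteoblasts and OMP, 17 of 25 genes of the osteoblast list were higher in osteoblasts and 12 of 26 fin mesenchyme genes were lower. Scpp1, which encodes a secretory calcium-binding phosphoprotein, stood at 282 CPM ± 38.9 against 0.570 ± 0.355 (log2 fold change 9.03, SE 0.50, edgeR adjusted p = 1.64e-05 with Benjamini-Hochberg adjustment). Cadm1b had 843 reads against 2 (563.9-fold, counting interval 155.6 to 4664). Mmp20b (8.92), the carbonic anhydrase gene cahz (8.72), bglapl (8.42), the fibrillar collagen gene col11a2 (8.30), megf10 (8.05) and the type V collagen gene col5a2b (8.03) followed. Lower in osteoblasts were the serotonin transporter slc6a4a (0 reads against 166, at least 41.4-fold), lrrc32 (1 read against 665, 497.0-fold, interval 88.9 to 19661), fmodb (0 against 118, at least 29.4-fold) and the BMP antagonist chrdl2 (1 against 681, 509.0-fold, interval 91.0 to 20134). They were joined by rgs5a (1 against 417, 311.7-fold, interval 55.6 to 12340), the transglutaminase tgm2b (-7.64), the BMP antagonist nbl1 (-7.54, 2.65 CPM ± 1.80 against 469 ± 59.3) and the chemokine ccl44 (1 against 261, 195.1-fold, interval 34.7 to 7734). Bounds are set against 3 reads over the group. Of 13399 genes, 431 were higher and 656 lower in osteoblasts, 808 of them at least 4-fold, and 794 and 1111 with the replicate block. Without 1 library, 582 (osteoblast replicate 2), 669 (OMP replicate 2), 713 (OMP replicate 1) and 727 (osteoblast replicate 1) of the 1087 stayed called, and without either CMP library 899 and 915.

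Of 25 osteoblast genes, 17 were higher in osteoblasts than in OMP and alpl, the tissue-nonspecific alkaline phosphatase, was lower (36.4 CPM ± 9.09 against 129 ± 44.7, -1.83, SE 0.43). Bglap reached 58340 CPM ± 4105 (5.52), col10a1b 92305 ± 21870 (5.72) and col10a1a 45699 ± 6815 (6.04). The mineralisation genes ifitm5 (7.86), panx3 (7.75), phospho1 (6.13) and entpd5a (4.72), the transcription factors mef2ca (2.71), runx2b (1.82), dlx5a (1.71) and dlx3b (1.55), and phex (2.64) and spp1 (2.17) also rose. Fgf23, which regulates phosphate, had 39 reads against 0 (at least 17.4-fold). The list's median was 2.64 (camera adjusted p = 5.04e-19, and adjusted p = 0.0521 with an estimated correlation), and 19 were higher and 1 lower adjusted over the list alone. Cdh11 was not called (0.98, SE 0.28, adjusted p = 0.0643), but was with the replicate block (adjusted p = 0.00214). Of the 18 calls, 15 were left without OMP replicate 2 or osteoblast replicate 1 and 16 without OMP replicate 1 or osteoblast replicate 2, with losses among alpl (adjusted p up to 0.197), fgf23 (0.173), mef2ca (0.0729) and dlx3b (0.0608).

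Fibrous matrix and fin mesenchyme genes were more often called lower than higher in the same comparison. Of 26 matrix genes, 5 were higher in osteoblasts, among them col5a2b, the biglycan genes bgnb (7.11) and bgna (5.36), and 13 lower, among them postnb (-3.73), or 6 and 15 adjusted over the list alone. Their median was -1.70, with camera adjusted p = 2.03e-04 (adjusted p = 0.360 with an estimated correlation). Of 29 collagen processing genes 6 were higher, such as plod2 (4.19), p4ha1b (1.90) and pcolcea (1.83), and loxl1 (-3.45) was lower, the same counts adjusted over the list alone, with 8 and 3 under the block. The processing list had a median of 0.44 (camera adjusted p = 0.00115, and adjusted p = 0.231 with an estimated correlation). Of 26 fin mesenchyme genes 12 were lower, led by pah (28.7 CPM ± 5.25 against 1071 ± 56.3, -5.23), hgd (-3.15) and qdpra (-4.22), enzymes of phenylalanine and tyrosine metabolism or of its cofactor, and vimentin, vim (-2.50), while dpt (2.81) was higher. The mesenchyme list had a median of -1.52 (camera adjusted p = 3.99e-11, adjusted p = 0.0720 with an estimated correlation) and 1 higher and 15 lower members adjusted over the list alone. Cartilage genes went both ways, with col11a2, sox6 (3.72) and col11a1b (2.2) higher and col2a1b (-1.89), matn4 (-1.84) and col11a1a (-1.80) lower among 12. The cartilage list had a median of -0.59 (camera adjusted p = 0.550), and 3 and 5 members adjusted over the list alone. The call of col2a1b was lost without osteoblast replicate 2 (adjusted p = 0.0627), and that of sox6 without OMP replicate 2 (0.0517). Lost too were those of p4ha1b and pcolcea without OMP replicate 1 (0.0553 and 0.0688) and that of pcolcea also without osteoblast replicate 2 (0.0609).

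Among signalling genes, 10 of 32 Wnt genes were lower in osteoblasts than in OMP, such as sfrp1b (-5.84), wnt5a (-4.34), sfrp1a (-3.59) and sfrp2 (-3.48), and 2 higher. The Wnt list had a median of -0.91 (camera adjusted p = 6.42e-04, and adjusted p = 0.250 with an estimated correlation), with 4 higher and 15 lower adjusted over the list alone and 4 and 12 under the block. Of 19 retinoic acid genes 8 were lower, such as rdh10a (-4.48), crabp2a (-3.34), cyp26b1 (-3.22) and crabp1b (-2.31), and 2 higher. The retinoic acid list had a median of -1.39 (camera adjusted p = 1.95e-04, adjusted p = 0.250 with an estimated correlation), with 2 and 10 adjusted over the list alone. Of 14 Hedgehog genes the ligand gene ihha (3.24) was higher and 4 were lower, hhip (-4.12), gli2b (-3.23) and gas1a (-2.45) among them. The Hedgehog list had a median of -0.75 (camera adjusted p = 0.00729, adjusted p = 0.594 with an estimated correlation), with 1 and 6 adjusted over the list alone and under the block. Of 27 BMP genes 8 were higher, such as the antagonist bmper (4.16), bambib (2.81) and bmp2b (2.62), and 3 lower, such as grem2b (-4.11), the same counts adjusted over the list alone. The BMP list had a median of 0.60 (camera adjusted p = 0.00973, adjusted p = 0.250 with an estimated correlation). Receptor genes fgfr4 (2.65) and fgfr3 (2.43) were higher and 4 of 23 FGF genes lower, such as fgf7 (-3.43) and il17rd (-2.77). The FGF counts were 4 and 5 adjusted over the list alone and under the block (camera adjusted p = 0.427). Of 19 Notch genes dld (2.99) was higher and dll4 (-3.08) and rfng (-1.72) lower, with 3 and 3 adjusted over the list alone and under the block. The Hedgehog list lost its call without OMP replicate 1 (adjusted p = 0.0741) and ihha without OMP replicate 2 (0.0629). Calls were also lost for dld without OMP replicate 2 (0.0951) or osteoblast replicate 1 (0.0937), and rfng without any OMP or osteoblast library (0.0838 to 0.196).

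Cell cycle genes were lower in osteoblasts than in OMP as a list (median -0.93, camera adjusted p = 0.00973, adjusted p = 0.566 with an estimated correlation). Kif20a (-3.10) and mcm4 (-1.32) were called among 28, the same adjusted over the list alone. That list lost its call without OMP replicate 2 (median -0.38, adjusted p = 0.175) or osteoblast replicate 1 (0.151), and mcm4 lost its own when any library was left out (0.0807 to 0.276). Klf2b (5.05) and egr3 (2.76) were higher among 32 early response and heat shock genes (2 and 1 adjusted over the list alone, 6 and 2 with the replicate block), as were the tendon genes tnmd (3.58) and mkxa (3.31) among 9 (3 and 2 with the block). Egr3 was lost without OMP replicate 2 (adjusted p = 0.143) or osteoblast replicate 1 (0.125). Nuclear oxidative phosphorylation genes had a median of 0.27 and no member called among 94 (camera adjusted p = 0.00299, adjusted p = 0.738 with an estimated correlation). They lost the list call without OMP replicate 1 (adjusted p = 0.570) or osteoblast replicate 2 (0.659). Cx43 (1.29) was the only fin joint gene called among 9 (2 adjusted over the list alone, 2 and 1 with the block), lost when any library but osteoblast replicate 2 was left out (adjusted p 0.0550 to 0.220). No posterior Hox or ribosomal protein gene was called, with none adjusted over those 2 lists alone.

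Some genes of other cell types were also called in this comparison. The keratin genes krt4 (-1.67), krt15 (-1.67) and krt91 (-1.65) and the periplakin gene ppl (-2.83) were lower in osteoblasts among 20 epidermal genes, the same 4 adjusted over the list alone (camera adjusted p = 0.133). Krt4 alone was left without OMP replicate 1 or osteoblast replicate 2, where adjusted p reached 0.143 and 0.240 for krt15. Krt15 was lost without either CMP library and without OMP replicate 2 (0.0644 to 0.0701), and krt91 without OMP replicate 2 (0.0524). Of 12 mural cell genes 4 were lower, namely rgs5a, acta2 (-3.96), tagln (-2.97) and rgs5b (-2.35), with 1 higher and 7 lower adjusted over the list alone. The mural list's median was -1.94, or -1.67 with its member at 0 reads set to its bound (camera adjusted p = 0.00894, and adjusted p = 0.510 with an estimated correlation). Of 3 pigment cell genes ltk (-3.73) and alx4a (-2.99) were lower (camera adjusted p = 0.00729, adjusted p = 0.250 with an estimated correlation). The list call was lost without either CMP library, OMP replicate 1 or osteoblast replicate 2 (adjusted p 0.0687 to 0.409), and that of alx4a without OMP replicate 1 (0.106), osteoblast replicate 1 (0.114) or osteoblast replicate 2 (0.0784). Tnfrsf11a (1.82), the RANK receptor, was higher among 5 osteoclast genes, mylz3 (5.22) among 3 muscle genes and cahz among 6 erythrocyte genes. No leukocyte (8), endothelial (3) or nerve and glia (6) gene was called. The call of tnfrsf11a was lost without OMP replicate 2 (adjusted p = 0.0962) or osteoblast replicate 1 (0.0714). Adjusted over the list alone, 2 endothelial genes were higher and 1 lower, and 1 osteoclast gene was lower. Under the block 1 leukocyte and 1 osteoclast gene were lower, 2 endothelial genes higher, 1 nerve gene higher and 1 lower, and 1 mural gene higher and 5 lower. The muscle median was 5.22, or 1.84 with its member at 0 reads set to its bound.

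Between osteoblasts and CMP 1424 genes were called, with 17 of 25 osteoblast-list genes higher and 13 of 26 fin mesenchyme genes lower. Znf385c had 551 reads against 0 (at least 260.0-fold). Col5a2b stood at 5046 CPM ± 1210 against 3.43 ± 2.02 (log2 fold change 10.56, SE 0.66, edgeR adjusted p = 1.21e-05 with Benjamini-Hochberg adjustment), and bglapl (10.00), mmp20b (9.78) and col11a2 (9.65) followed. Among the 8 were also megf10 (1202 reads against 1, 1701.5-fold, interval 304.8 to 67261), cahz (2073 against 2, 1467.2-fold, interval 405.7 to 12124) and cadm1b (843 against 1, 1193.3-fold, interval 213.6 to 47189). With the same abundance and name limits, the largest falls were those of fmodb (0 reads against 1104, at least 260.0-fold), slc6a4a (0 against 832, at least 195.9-fold), and2 (3 against 4397, 1035.4-fold, interval 354.1 to 5023) and chrdl2 (1 against 822, 580.7-fold, interval 103.9 to 22964). They also included lrrc32 (1 against 589, 416.1-fold, interval 74.4 to 16462), rgs5a (1 against 637, 450.0-fold, interval 80.5 to 17802), the leptin gene lepb (2 against 889, 314.0-fold, interval 86.7 to 2597) and cyp1c1 (3 against 1232, 290.1-fold, interval 99.0 to 1409). In all, 610 genes were higher and 814 lower, 1096 of them at least 4-fold, and 1062 and 1361 with the replicate block. Of these 1424, 748 stayed called without CMP replicate 2, 801 without osteoblast replicate 2, 847 without CMP replicate 1 and 981 without osteoblast replicate 1.

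The osteoblast list had 17 members higher and msx2b (-4.03), dlx4b (-3.65) and the osteomodulin gene omd (-4.89) lower, and 17 and 5 adjusted over the list alone. Its median was 3.93, with camera adjusted p = 1.06e-12 (adjusted p = 0.0746 with an estimated correlation). Col10a1a (8.45), bglap (8.28), spp1 (4.81), cdh11 (3.93), runx2b (2.55) and runx2a (2.22) were among the 17, and alpl stood at -0.64 (SE 0.43, adjusted p = 0.482). Of these 20 calls, 18 were left without CMP replicate 1, 16 without CMP replicate 2 and 17 without osteoblast replicate 1. Losses were among runx2a (adjusted p up to 0.130), fgf23 (0.126), omd (0.103) and mef2ca (0.0522). Of 26 matrix genes 7 were higher, bgna (8.39), bgnb (5.90) and col5a2b among them, and 14 lower, such as fmodb, or 7 and 18 adjusted over the list alone. The matrix median was -1.76 (camera adjusted p = 0.00256, adjusted p = 0.447 with an estimated correlation). Collagen processing genes loxl3a (3.48), loxa (3.34), p4ha1b (2.71) and plod2 (2.39) rose among 6 higher and 1 lower of 29, with 9 and 1 adjusted over the list alone and 16 and 2 under the block. The processing median was 0.69 (camera adjusted p = 6.74e-06, adjusted p = 0.101 with an estimated correlation). Of 26 fin mesenchyme genes 13 were lower, such as and2, cyp26b1 (-5.38), pah (-3.86) and vim (-3.47), and 14 adjusted over the list alone. The mesenchyme median was -1.26 (camera adjusted p = 7.36e-11, adjusted p = 0.0746 with an estimated correlation). Cartilage genes col11a2, sox6 (2.36) and col11a1b (1.80) were higher and hapln1a (-3.55), sox9a and matn4 (-1.51) lower among 12, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.282). Sox6 lost its call without CMP replicate 1 (adjusted p = 0.155), CMP replicate 2 (0.0621) or osteoblast replicate 1 (0.130). Calls were lost for matn4 without CMP replicate 2 (0.126) or osteoblast replicate 1 (0.0920), and sox9a without CMP replicate 1 (0.0741) or osteoblast replicate 2 (0.0890).

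Of 9 fin joint genes evx1 (3.40), prg4a (2.38) and pth1ra (2.70) were higher and hapln1a, gdf6a (-1.79) and gdf5 (0 reads against 51, at least 12-fold) lower in osteoblasts than in CMP. The joint counts were 4 and 5 adjusted over the list alone and 3 and 5 under the block, and gdf5 was lost without CMP replicate 1 (adjusted p = 0.0726), osteoblast replicate 1 (0.0654) or osteoblast replicate 2 (0.137). Hoxb13a (3 reads against 191, 45.0-fold, interval 15.2 to 220) was the only posterior Hox gene called among 18, with 2 called under the block. It was lost without CMP replicate 1 (adjusted p = 0.0508) or osteoblast replicate 2 (0.0619). Of 32 Wnt genes 11 were lower, such as wnt5a (-5.86), frzb (-5.37), sfrp1a (-4.0) and rspo1 (2 reads against 226, 79.8-fold, interval 21.8 to 663), and 2 higher. With 4 and 12 adjusted over the list alone and 5 and 13 under the block, the Wnt median was -0.81 (camera adjusted p = 0.00292, adjusted p = 0.442 with an estimated correlation). Of 27 BMP genes bmper (5.64), bmp3 (5.52) and bmp2b (5.36) were among 6 higher and nog1 (-5.08) among 3 lower. The BMP counts were 8 and 4 adjusted over the list alone and 8 and 5 under the block (camera adjusted p = 0.0844). Fgfr4 (4.47) was among 4 higher and fgf7 (-4.12), fgfrl1a (-3.19) and fgf18a (1 read against 131, 92.5-fold, interval 16.3 to 3683) among 6 lower of 23 FGF genes. FGF counts were 6 and 9 adjusted over the list alone and 6 and 7 under the block (camera adjusted p = 0.339). Of 14 Hedgehog genes ihha (3.93) was higher and 5 were lower, such as gas1a (-3.11), the same adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.461 with an estimated correlation). Of 19 retinoic acid genes 8 were lower, such as the retinaldehyde dehydrogenase genes aldh1a2 (-5.54) and aldh1a3 (2 reads against 220, 77.7-fold, interval 21.3 to 646), and 1 higher. The retinoic acid counts were 2 and 8 adjusted over the list alone and 2 and 9 under the block (camera adjusted p = 0.00111, adjusted p = 0.442 with an estimated correlation). Dld (5.39) and heyl (3.76) were higher and 3 Notch genes lower of 19, with 5 and 3 adjusted over the list alone and under the block. Rfng (-1.79) and dll4 (-2.27) were lost without CMP replicate 2 (adjusted p = 0.245 and 0.0557), osteoblast replicate 1 (0.112 and 0.134) or osteoblast replicate 2 (both 0.138), and dll4 also without CMP replicate 1 (0.151).

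Cell cycle genes were lower in osteoblasts than in CMP as a list (median -1.11, camera adjusted p = 0.00178, adjusted p = 0.447 with an estimated correlation). Of 28, 0 were called by edgeR over all genes or over the list alone and 5 lower under the block. Klf2b (5.71) and egr3 (3.36) were among 3 higher and socs3b (-1.83) and socs3a (-1.33) among 3 lower of 32 early response and heat shock genes, with 5 and 3 adjusted over the list alone and 7 and 6 under the block. Lost calls included egr3 without CMP replicate 2 (adjusted p = 0.0834), socs3b without CMP replicate 1 (0.0623) or osteoblast replicate 2 (0.0755), and socs3a without any CMP or osteoblast library (0.0814 to 0.149). Tendon genes tnmd (3.66), mkxa (3.42) and scxa (2.42) were among 4 higher and thbs4a (-3.46) among 2 lower of 9, the same adjusted over the list alone (camera adjusted p = 0.00846, adjusted p = 0.461 with an estimated correlation). Ribosomal protein genes had median -0.29 (camera adjusted p = 0.00208) and nuclear oxidative phosphorylation genes 0.32 (camera adjusted p = 0.00289), with 0 of 81 and 0 of 94 called, and adjusted p = 0.635 with an estimated correlation for both. The ribosomal call was lost without osteoblast replicate 1 (adjusted p = 0.307), and the oxidative phosphorylation call without CMP replicate 1 (0.120) or osteoblast replicate 2 (0.545). Of 20 epidermal genes krt4 (-2.54), krt15 (-2.84) and krt91 (-2.43) were lower, 4 adjusted over the list alone and 6 under the block (camera adjusted p = 0.138). Of 12 mural cell genes 7 were lower, such as acta2 (-6.75) and tagln (-4.2), and 1 higher (camera adjusted p = 0.00104, adjusted p = 0.442 with an estimated correlation, 2 and 7 adjusted over the list alone).

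Mmp9 (2.59) was higher and grn1 (2 reads against 62, 21.9-fold, interval 5.8 to 185) lower among 8 leukocyte genes in osteoblasts against CMP. Tnfrsf11a (2.35) was higher among 5 osteoclast genes and erg (2.07) among 3 endothelial genes. Syt1a (3.06) was higher and plp1b lower (3 reads against 59, 13.9-fold, interval 4.5 to 69.3) among 6 nerve and glia genes. Higher too were mylz3 (283 reads against 3, 133.5-fold, interval 45.2 to 651) among 3 muscle and cahz among 6 erythrocyte genes. No pigment cell gene of 3 was called, and 2 were lower adjusted over the list alone. Adjusted over the list alone, 1 further endothelial gene and 1 further nerve gene were lower. Under the block the same counts held for these 2 lists, 2 leukocyte genes were lower, and 1 pigment cell gene was lower. The calls of grn1 (adjusted p 0.0750 to 0.246), plp1b (0.124 to 0.347) and syt1a (0.0662 and 0.0713) were lost without either CMP library and those of grn1 and plp1b also without osteoblast replicate 2. Plp1b was lost without OMP replicate 1 or OMP replicate 2 as well (0.0564 and 0.0553). Erg was lost without CMP replicate 2 (0.221) or either osteoblast library (0.0829 and 0.102).

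**Figure D4:**
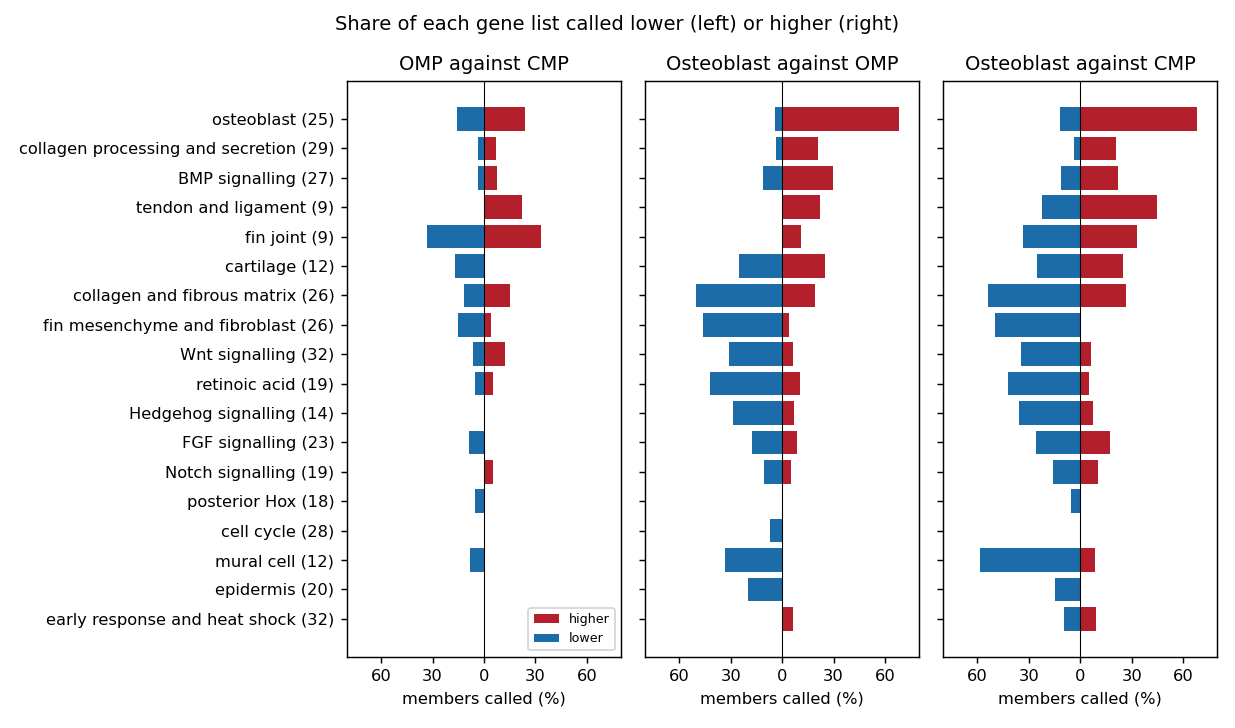
Share of the measured members of each gene list, their number in parentheses, called lower (left bars) or higher (right bars) in each of the 3 comparisons, in percent. The osteoblast list reaches the largest share of higher calls in both comparisons with osteoblasts, where 17 of 25 members were higher.

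The median, mean and camera direction did not share 1 sign for some lists, none of them called by camera. Besides cartilage, these were early response and heat shock, Wnt, BMP, FGF, osteoclast, endothelium and muscle in OMP against CMP. In osteoblasts against OMP they were fin joint, early response and heat shock, osteoclast and erythrocyte. In osteoblasts against CMP they were early response and heat shock, osteoclast, nerve and glia, muscle and erythrocyte.

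The position of OMP between the other groups was described by distances and by the overlap of calls against CMP. The root mean square difference of log2 CPM over 13399 genes averaged 1.03 between CMP and OMP (0.954 to 1.1), 1.39 between OMP and osteoblasts (1.28 to 1.47) and 1.51 between CMP and osteoblasts (1.41 to 1.57), over 4 pairs of libraries each. Between CMP and OMP of the same replicate number it was 0.954 and 0.979, and across numbers 1.094 and 1.098. It was 0.852, 0.930 and 0.956 between the replicates of CMP, OMP and osteoblasts, pairs that always cross numbers. The values of CMP and OMP across numbers lay above each of these. Same-number values lack any difference between the numbers, so they are not a like comparison. Of the genes called against CMP, 66 were higher and 101 lower in both OMP and osteoblasts. They included bglap, col10a1a, cdh11 and spp1 among the former and sox9a, hapln1a, msx2b and dlx4b among the latter. Simulated unchanged groups against the same CMP libraries shared 0.05 and 0 on average over 20 simulations, and independent lists of these sizes would share 6.01 and 7.84. No gene was changed in the simulations, so their counts of shared or opposite calls were fixed near 0 beforehand and measure no excess. With the replicate block the counts were 185 and 309, and without CMP replicate 2 and CMP replicate 1 they fell to as few as 5 higher and 5 lower. Opposite calls were made for 21 genes (0 simulated, 13.9 for independent lists). The covariance of the log2 fold changes was 0.766 against 0.257 in the simulations, a difference of 0.509. Their correlation across genes, which are not independent replicates, was 0.459 against 0.484, and so was not above the simulations. The shared CMP libraries alone gave the simulated value, and changes in only 1 group lower a correlation. It therefore speaks neither for nor against changes common to OMP and osteoblasts. Both comparisons use the same 2 CMP libraries, too few to be parted, so part of the excess may come from the shared controls.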

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

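The sum of transcripts, DESeq2 with the replicate block and the counts with early response and heat shock genes left out before filtering were chosen after seeing the data, and all other alternatives before. Of the single-gene fold changes under all alternatives, 7732 stayed on their side of the threshold, 324 lost a call, 159 gained one and 0 reversed. Of the list results 839 kept their call status, 22 lost a call, 19 gained one and 2 reversed in sign past the threshold. Signs of genes or lists were not compared where neither fit made a call. Of the counts 105 stayed within 1.5 times, 20 grew and 33 shrank. No rescaling moved the median fold change of all genes by over 0.1 (at most 0.0215). Unless stated, the cause was not tested. Leaving out a library leaves its group with 1, which is then assumed to vary like the other groups. Those fits did not include the replicate block.

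The replicate block takes up a difference between the replicate numbers, and raised the counts to 418 higher and 400 lower in OMP against CMP, 794 and 1111 in osteoblasts against OMP, 1062 and 1361 in osteoblasts against CMP, and 185 and 309 genes higher or lower than CMP in both. It ended the posterior Hox call in OMP against CMP (median -0.52, adjusted p = 0.0985) and changed no other call of a list. DESeq2 with the replicate block gave 366 and 314, and 656 and 1002 in osteoblasts against OMP.

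For OMP against CMP (132 higher, 129 lower), DESeq2 gave 230 and 196, no filter 203 and 195, and a test against a fold of 1.5, which asks for larger changes, 78 and 79. The legacy dispersion gave 83 lower and the sum of transcripts 85 lower. Without a filter 158 genes were lower than CMP in both, and the distances, averaged over more genes, were 1.23 between OMP and osteoblasts and 1.32 between CMP and osteoblasts. The sp7 call in OMP against CMP was lost with limma-voom (2.09, adjusted p = 0.155), only the 2 groups (2.14, 0.128), a fold of 1.5 (2.15, 0.0719) and the sum of transcripts (2.15, 0.0922), and the sox9a call with the sum (-2.37, 0.0523). Without a filter posterior Hox in OMP against CMP (-0.22) and pigment cell in osteoblasts against OMP (-0.30) lost their calls and leukocyte in osteoblasts against CMP (-2.55) gained one. The strict filter ended the posterior Hox call (-0.45) and gave calls for epidermis against OMP (-0.52) and CMP (-0.53).

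With each library left out in turn, counts ranged from 6 to 138 higher and 5 to 148 lower in OMP against CMP, 221 to 378 and 317 to 564 in osteoblasts against OMP, 284 to 638 and 404 to 837 in osteoblasts against CMP, and 5 to 60 and 5 to 116 for genes higher or lower than CMP in both. The share of higher calls in OMP against CMP, 50.6% with all libraries, was 61.5% without CMP replicate 1, 64.2% without OMP replicate 1 and 69.1% without OMP replicate 2. For sp7 in OMP against CMP log2 fold changes ranged from 1.97 to 2.31, for sox9a from -2.71 to -2.06 in OMP and -2.54 to -1.91 in osteoblasts against CMP. List medians ranged, in OMP against CMP, from -0.69 to -0.013 (cell cycle), -5.33e-06 to 0.44 (fibrous matrix), 0.085 to 0.35 (collagen processing), -1.49 to -0.53 (mural cell), 0.40 to 1.44 (pigment cell), -0.55 to -0.27 (posterior Hox), -0.33 to -0.12 (ribosomal protein) and 0.21 to 0.84 (tendon). In osteoblasts against OMP they ranged from -0.99 to -0.38 (cell cycle), -0.59 to 0.81 (early response and heat shock), -0.71 to 0.37 (epidermis), -1.07 to -0.45 (Hedgehog), 0 to 5.29 (muscle), -0.016 to 0.55 (oxidative phosphorylation) and -4.68 to -0.70 (pigment cell). In osteoblasts against CMP the ranges were -0.66 to 0.48 (early response and heat shock), -0.66 to 0.083 (epidermis), 0.042 to 0.58 (oxidative phosphorylation) and -0.40 to -0.16 (ribosomal protein). In OMP against CMP, 2 lists with no call in all libraries were called in opposite directions without 1 OMP library or the other. Early response and heat shock had a median of -0.69 without OMP replicate 1 (adjusted p = 0.00117) and 0.41 without OMP replicate 2 (0.0249). Oxidative phosphorylation had 0.25 (0.0286) and -0.29 (0.0337). Other lists with a call only when a library was left out were fibrous matrix, collagen processing, tendon, cell cycle and pigment cell in OMP against CMP. In osteoblasts against OMP they were epidermis, early response and heat shock and muscle, and in osteoblasts against CMP epidermis and early response and heat shock.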

Other observations

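All tests in the weighing of patterns were chosen after the results were seen, and the genes named first were chosen after their values were seen.

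A set of 54 genes was called higher in OMP than in both other groups, against 6.46 for independent lists of these sizes. Simulated groups with no changed gene gave 0, a value fixed beforehand that measures no excess. Both comparisons use the same OMP libraries, so part of the excess may come from them. Among its members were the periostin gene postnb (1381 CPM in CMP, 7834 in OMP and 589 in osteoblasts, means of n = 2), the matrix Gla-type gene ucmaa (431, 2908 and 130), the Wnt antagonists sfrp2 (424, 1111 and 99.7) and wif1 (226, 994 and 287), and the phenylalanine hydroxylase gene pah (416, 1071 and 28.7) with its cofactor enzyme gene pcbd1 (121, 371 and 45.2). Mamdc2b (282, 920 and 15.99), the chemokine ccl25b (95.3, 827 and 25.4), aebp1 (114, 699 and 173), the heparan sulfate sulfatase sulf1 (47.0, 520 and 88.5), the collagen genes col7a1 (89.2, 410 and 141) and col5a3b (65.9, 251 and 3.03), and the BMP antagonist grem2b (27.1, 159 and 9.13) were also highest in OMP. The Wnt antagonists dkk2 (0.75, 17.6 and 0.393) and notum1b (93.6, 243 and 37.5) and the ligand wnt16 (0.693, 14.2 and 3.14) belonged to the set. With the replicate block the count was 200, without CMP replicate 1 it was 0, without CMP replicate 2 it was 1, and without OMP replicate 1 it was 29.

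Only 15 genes were called lower in OMP than in both other groups (4.15 for independent lists, and 0 simulated, where no gene was changed). They include the homeobox genes dlx3b (543 CPM in CMP, 95.2 in OMP and 278 in osteoblasts) and dlx5a (229, 67.1 and 220), the connexin gene cx43 (418, 92.1 and 225), dpt (371, 60.7 and 428), the lysyl hydroxylase gene plod2 (88.2, 25.4 and 461), chad (108, 30.6 and 265) and nfixb (560, 227 and 550). The count was 57 with the replicate block, 0 without CMP replicate 1, 1 without CMP replicate 2, 5 without OMP replicate 1 and 3 without OMP replicate 2.

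Of 25 osteoblast-list genes 6 were called higher and 4 lower in OMP than in CMP, mCherry was not called, and carry-over of osteoblasts into the OMP sort was weighed for the 6. From osteoblasts to OMP, cdh11, spp1, sp7 and bglap fell less than mCherry, by at least 2.22 on the log2 scale (bglap, SE of the difference 0.98), which argues against cells that express mCherry as their whole source. For col10a1a (1.69, SE 0.98) and col10a1b (2.01, SE 1.03) the 95% interval of the difference held 0 in this fit without the replicate block. Within replicates 1 and 2, OMP held 1.94% and 1.18% of the osteoblast level of col10a1a and 2.57% and 1.41% of that of col10a1b. For mCherry it held 0.204% and 0.53%, with upper 95% counting limits of 0.445% and 0.68%. The shares of both genes thus lay above that of mCherry in both replicates, but these limits cover counting error only. No paired test was run, so the values do not decide whether mCherry-expressing cells were the whole source of both genes. Another 21 transcripts of at least 1000 CPM in osteoblasts were called higher there than in OMP. For each of the 6 genes, 5 or more of these fell further, with 95% intervals of the difference above 0. Bglapl, col11a2, col5a2b and ifitm5 were among them. This argues against cells with the profile of the sorted osteoblasts as the whole source of the level of the 6 genes in OMP. The 6, picked as higher in OMP than in CMP, were kept out of the 21, and the CMP level was not subtracted. That OMP cells express a part of the osteoblast genes, or that the sort holds another cell kind that does, may each account for the values, and neither was tested.

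Keratin genes krt4, krt15 and krt91 fell in osteoblasts against CMP, and a smaller carry-over of epidermal cells was weighed. Of 6 other epidermal transcripts with a mean log2 CPM of at least 4, 5 had 95% intervals above the smallest fall of the 3 keratins (-2.43), among them krt5, which did not fall (0.66), and icn (-0.55, 7796 CPM in CMP and 5339 in osteoblasts). This argues against a smaller share of epidermal cells with all their transcripts as the whole cause. The 3 keratins were picked because they were called lower, so that others fell less follows in part from that choice. The error of their smallest fall (krt91, SE 0.389) was not counted. A change in which epidermal cells were carried over, or expression of these keratins by the sorted cells themselves, may account for it and was not tested.

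The reporter reads did not follow the sort status in the titles. An exchange of the OMP and osteoblast libraries was weighed with sp7, which was higher in the libraries labelled osteoblast (log2 fold change 4.16), as was mCherry. Both titles give an sp7-positive sort, so these values cannot by themselves decide it. After an exchange the libraries labelled osteoblast, with EGFP and mCherry reads, would match the OMP title. Those labelled OMP would still go against an EGFP-negative, sp7-positive sort, so an exchange alone would not match all reads to the titles. Carry-over as the source of EGFP in osteoblasts is argued against by its level, 91.7% and 118% of that in CMP in replicates 1 and 2. The submitters' short names Mes-G, Ob-G and Ob-GR would match the reads if G and R stand for green and red, which the labels do not state. A gate written in the titles that differs from the gate used, and reporter RNA that does not follow reporter protein, may each account for the values, and neither was tested.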
